A study of Mus musculus with 3 samples.

How the data were processed

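RNA sequencing of macrophages sorted from the spleens of mice with acute myeloid leukemia was analysed in 3 libraries, 1 from each group: leukemia with a high level of mM-CSF, leukemia with a high level of sM-CSF, and control leukemia with neither. Per the labels' protocols, 1 ug of total RNA went into each library and sequencing was done on a BGISEQ-500 instrument. The submitters' processing notes name Bowtie2 (version 2.2.5) and RSEM, without giving the role of either. The genome build and annotation were not given in the sources used here, so no genomic coordinates are printed.

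Each deposited table holds, per NCBI gene ID and per the file headers, an expected count, a gene length and an FPKM value. The expected count is the authors' estimate of the reads belonging to a gene, as RSEM gives it, and need not be whole: 75.7%, 76.7% and 75.9% of the listed counts in the control, mM-CSF and sM-CSF libraries were whole within 0.005 reads. A count that is not whole can arise where reads are divided between genes, and values of near-identical copies and overlapping genes (Hspa1a and Hspa1b, the Cd300ld family, Csf2rb and Csf2rb2, Lyz2, Ly6c1 and Ly6c2, Bcl2a1a and Bcl2a1d, Stfa1, globins, histones, Evi2, Pbld1, Pcsk1n, Itgam, Cx3cr1) are uncertain. Whether counting used the strand was not given in the sources used here, so Xist and its antisense partner Tsix cannot be separated with certainty. The deposited FPKM values had been scaled by the authors to the library's mapped fragments, and genes not listed in a table were taken as 0. Listed genes accounted for nearly all of each library, since 1.82%, 2.02% and 1.90% of the implied FPKM denominator lay outside them.

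The tables listed 17615 genes in any library, of which all but 54 received a symbol through a reference table of the GRCm38.p6 assembly, which was used for names and for the order of neighbouring genes. Total estimated counts were 9.09e+06 (control), 8.57e+06 (mM-CSF) and 8.94e+06 (sM-CSF). A floor of 3 counts corresponds to 0.330, 0.350 and 0.335 CPM in these libraries.

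With 1 library per group there is no replicate spread, so no test between conditions and no p-value was possible, and every difference describes these libraries. Differences were taken between values of log2(FPKM + 1), a scale that understates the change of low genes. A gene was counted as higher or lower when the difference was at least 1 in size (2-fold) and the higher library had at least 5 FPKM. For single genes, the ratio of the shares of counts in both libraries was given an exact conditional (Clopper-Pearson) 95% interval, which covers counting error only. Against a count of 0, the fold was computed with a floor of 3 counts in that library, and the lower 95% limit is given beside it.

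Choices made before the data were examined were the size rule, the named genes, 30 lists of macrophage processes, 15 lists of markers of other cell types, and the alternatives on pseudocount, minimum, scaling and size rule. Of the 719 list genes, 699 matched a gene in the tables. Lists share members (Itgax is in 3 of them, and 5 of 12 non-classical monocyte, 6 of 13 conventional dendritic cell and 6 of 18 macrophage identity genes are in another list), so counts of lists are not counts of separate findings. The named genes were, among genes at 10 FPKM or more in the higher library, the 12 highest and the 12 lowest in each comparison with the control, and the 6 highest and 6 lowest between the mM-CSF and sM-CSF libraries, leaving out predicted models, ribosomal protein, mitochondrial and small RNA genes. Up to 4 members of each list with the largest difference and at least 5 FPKM in the higher library were added, with Csf1, Csf1r, Adgre1, Itgam, Mrc1, Ly6g, Kit and sex-linked genes in every comparison. C1qc and Hba-a1, the level of a gene in a library outside the comparison that named it, and Pcsk1n outside the comparison of sM-CSF with control were chosen after the values were seen.

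For each list, members at 1 FPKM or more in either library were measured, and the median difference was placed as a percentile among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the 2.5 or above the 97.5 percentile, where 5% of lists of randomly drawn genes lie. Genes of a fixed list can change together, which random lists do not copy. The 5% is thus not an error rate for differences between conditions. After the data were seen, a trend of the differences with gene length led to further settings: the running median of the difference over 20 length bins was subtracted, random lists were also matched on length (drawn from the 100 genes nearest in length within the same of 5 equal-sized expression bins, without ribosomal protein genes), genes under 300 bases were left out, and a minimum of 5 FPKM was applied to lists.

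The counting steps were tested on simulated libraries of 16470 genes. In the mM-CSF and control simulation, 97.5% of genes raised 2.5-fold and 90% of genes set to 0.4-fold were called, against 0.246% of unchanged genes. In the sM-CSF and control simulation the shares were 100%, 92.5% and 0.264%, and between mM-CSF and sM-CSF they were 97.5%, 92.5% and 0.258%. Simulated counts were drawn from the control library's means with counting error only. They held no other spread between libraries and no length trend, so these shares are not error rates of the real comparisons. Because both comparisons with the control share 1 library, their correlation and overlap were set beside values simulated with no effect. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.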

Results

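Macrophages were profiled by RNA sequencing in C57BL/6J mice carrying an acute myeloid leukemia marked with GFP and BFP. The leukemia cells had a high level of mM-CSF, a high level of sM-CSF, or neither. M-CSF, the product of Csf1, is the growth factor that maintains macrophages through its receptor CD115, the product of Csf1r, and exists in membrane-bound and soluble forms. The labels do not spell out the prefixes. Each recipient, aged 6 to 8 weeks, received 800000 leukemia cells without irradiation, and such mice lived 30 to 40 days. Splenic macrophages that lacked GR1, had intermediate CD115 and carried F4/80 were sorted on day 18. There was 1 library per group, so none of the differences has a replicate check. Total estimated counts were 9.09e+06 in the control library, 8.57e+06 in the mM-CSF library and 8.94e+06 in the sM-CSF library, spread over 16470, 16194 and 16401 listed genes.

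The genes behind the sort were expressed in every library. Csf1r (NCBI gene 12978) was at 268 FPKM in the control, 222 in the mM-CSF and 149 in the sM-CSF library, and Adgre1 (gene 13733), which encodes F4/80, was at 101, 67.5 and 65.5 FPKM. Csf1 itself (gene 12977) was low in these cells, at 2.44, 1.45 and 2.32 FPKM. Mrc1, a mannose receptor of tissue macrophages, was at 42.5, 46.6 and 40.5 FPKM, and the neutrophil gene Ly6g did not pass 1.45 FPKM in any library. Transcripts of other cell types were abundant as well. The immunoglobulin joining chain gene Jchain was at 1008, 3301 and 1072 FPKM, the B cell receptor gene Cd79a at 468, 1117 and 958 FPKM, and the hemoglobin gene Hba-a1 at 2336, 1990 and 1659 FPKM. Across 11447 genes, Pearson's r of log2(FPKM + 1) was 0.98 between the sM-CSF and control libraries, 0.94 between the mM-CSF and sM-CSF libraries, and 0.90 between the mM-CSF and control libraries. Genes are not independent replicates in these correlations.

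**Figure D1:**
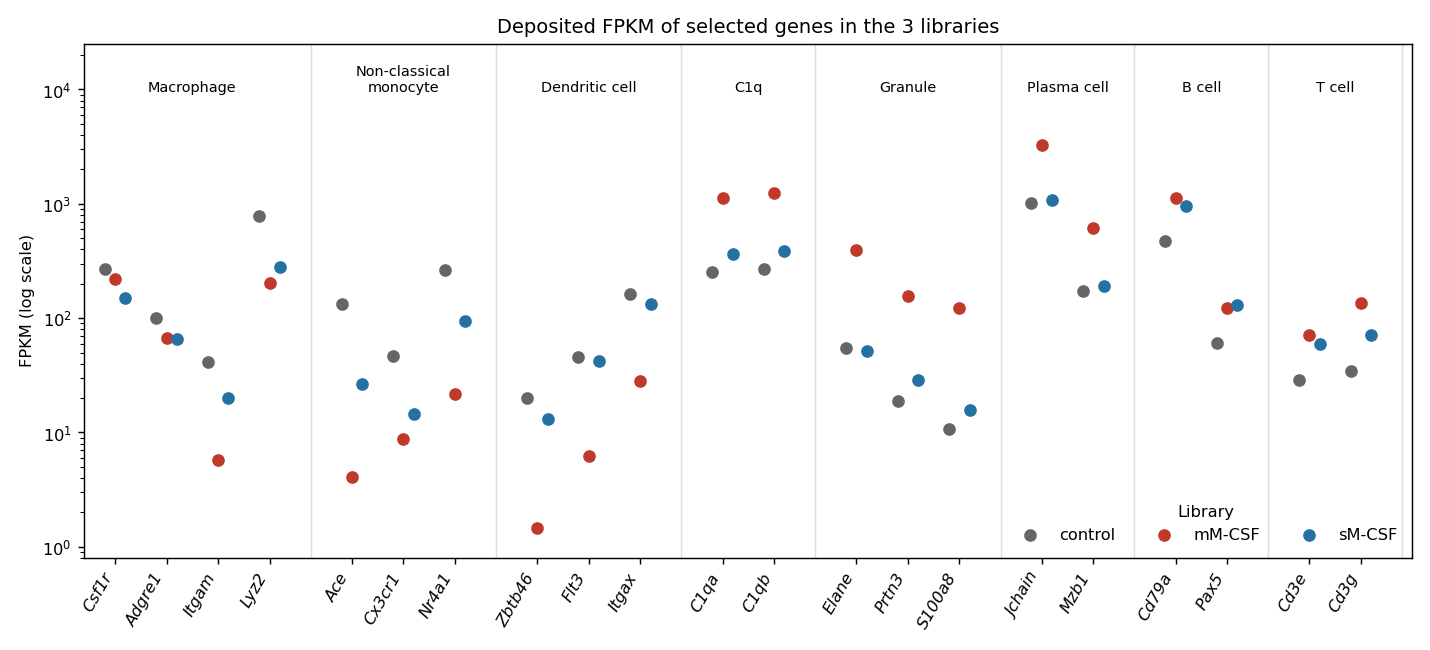
FPKM on a log axis of selected genes of the fixed lists, chosen for display after their values were seen, with 1 point per library (control grey, mM-CSF red, sM-CSF blue). Ace lies at 132 FPKM in the control, 26.5 in the sM-CSF and 4.09 in the mM-CSF library, while Elane lies at 397 FPKM in the mM-CSF library and near 50 in the others.

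The first comparison asks how macrophages from leukemia with high mM-CSF differ from those of control leukemia. Genes of non-classical monocytes, conventional dendritic cells, inflammatory signalling and stress were lower in the mM-CSF library, while genes of granule proteins, plasma cells, T cells, ribosomes and C1q were higher. Ace (gene 11421), an angiotensin-converting enzyme gene that marks non-classical monocytes, was at 132 FPKM in the control and 4.09 in the mM-CSF library, a 41.9-fold lower share of counts (95% interval 35.3 to 50.1). Elane (gene 50701), which encodes neutrophil elastase, was at 54.5 and 397 FPKM, 7.32-fold higher (6.63 to 8.11), a log2 difference of 2.84 that was 1.98 with the trend on gene length removed. By the size rule 878 genes were higher and 1480 lower among 9789 genes with the minimum expression.

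Among 12 measured non-classical monocyte genes, 8 were lower and 0 higher, with a median difference of -1.40 that lay below all 10000 matched random lists. Nr4a1, a transcription factor gene needed for these monocytes, was at 266 FPKM in the control and 21.7 in the mM-CSF library, and the chemokine receptor gene Cx3cr1 at 46.8 and 8.70. Conventional dendritic cell genes had the lowest median among lists with at least 4 measured genes, -2.00 over 13 genes, of which 9 were lower. Zbtb46, a transcription factor gene of these cells, was at 20.1 and 1.46 FPKM, the growth factor receptor gene Flt3 at 46.0 and 6.25, and the integrin gene Itgax at 163 and 28.1. With the length trend described later removed, both medians stayed low, at -1.82 and -1.72.

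Inflammatory genes were lower in several lists. The NF-kB feedback list had 6 of 16 genes lower and a median of -0.86, with Nfkbiz at 62.0 and 12.1 FPKM and Zfp36, an mRNA-destabilising factor, at 564 and 170. Of 16 classical activation genes 4 were lower and the median was -0.62, and the cytokine genes Il1b and Tnf were at 68.6 and 6.52 FPKM and at 37.0 and 10.3 FPKM. The toll-like receptor list (16 genes, 6 lower, median -0.92) included the nucleic acid sensors Tlr9, at 50.6 and 5.41 FPKM, and Tlr7, at 45.2 and 11.3. Of 30 type I interferon response genes 10 were lower and 1 higher, with a median of -0.69 and the antiviral gene Rsad2 at 14.7 and 3.07 FPKM. Chemokine genes had a median of -0.77, with 4 of 12 lower, among them Cxcl16 at 25.3 and 3.74 FPKM. The immediate early and heat shock list, which can also register handling of cells, had 8 of 19 genes lower and a median of -0.89. Atf3 was at 40.7 and 3.75 FPKM, Egr1 at 176 and 27.0, and the near-identical Hspa1a and Hspa1b at 92.3 and 107 FPKM in the control against 0.92 and 1.22. All 6 lists lay below the 2.5 percentile of random lists, and their medians with the length trend removed were -0.997, -0.86, -0.71, -0.73, -1.10 and -0.69 in the order given.

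Receptors of the colony-stimulating factors were lower for GM-CSF and G-CSF. In that list 4 of 7 measured genes were lower (median -1.11, percentile 0.33, and -0.71 with the length trend removed). Csf2ra was at 117 and 42.2 FPKM and Csf2rb at 54.9 and 13.1, and both stayed past 2-fold with the length trend removed (-1.73 and -1.33). The G-CSF receptor gene Csf3r was at 26.7 and 11.8 FPKM (-1.11), but short of 2-fold with the trend removed (-0.71). Csf1r differed by -0.27, and by 0.16 with the trend removed. Macrophage identity genes went both ways, with 2 of 18 higher, 4 lower and a median of -0.03 (-0.40 with the length trend removed) that lay within the random range. Itgam, which encodes CD11b, was at 41.3 and 5.76 FPKM, the lysozyme gene Lyz2 at 784 and 205, and the transcription factor gene Cebpb at 75.8 and 21.6, while Aif1 was higher, at 29.7 and 90.6 (a difference of 1.58, but 0.69 with the length trend removed). Of 12 MHC class II genes 2 were lower and the median was -0.05, at percentile 0.87, turning to 0.02 with median-of-ratios and 0.05 with upper-quartile scaling and to -0.69 with the length trend removed. Their transactivator gene Ciita was at 80.6 and 16.4 FPKM.

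C1q genes stood out within the complement list. C1qa was at 254 FPKM in the control and 1129 in the mM-CSF library, a 4.47-fold higher share of counts (95% interval 4.27 to 4.67), C1qb at 271 and 1231, and C1qc at 312 and 1085. With the length trend removed, the differences of C1qa and C1qb were 1.39 and 1.41 in place of 2.15 and 2.18. The list held 4 higher and 2 lower genes of 12, and its median of -0.68 (-0.04 with the length trend removed) turned to 0.88 when only members at 5 FPKM or more were kept. Of the 17 red pulp macrophage and iron handling genes 3 were higher and 1 lower, with a median of 0.41 within the random range (0.21 with the length trend removed). The transferrin gene Trf was at 114 and 614 FPKM and the ferritin gene Ftl1 at 1836 and 4201, while the transferrin receptor gene Tfrc was lower, at 50.3 and 16.2. Of the 3 higher genes, Trf stayed past 2-fold with the length trend removed (2.30), whereas Ftl1 (0.37) and the biliverdin reductase gene Blvrb (0.32) did not. Tfrc, the 1 lower gene, also fell short of 2-fold, going from -1.57 to -0.89.

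Markers of other cell types were higher for granulocytic and plasma cells. Of 8 myeloid granule genes 6 were higher, with a median of 1.71 above all random lists and 1.17 after removal of the length trend. Prtn3, which encodes proteinase 3, was at 18.8 and 158 FPKM, and Ctsg, for cathepsin G, at 18.8 and 92.3. Neutrophil genes had 5 of 13 higher and 1 lower (median 1.17, or 0.65 without the trend), with S100a8 at 10.7 and 122 FPKM. Plasma cell genes had 5 of 7 higher (median 1.71, or 0.98 without the trend), with Mzb1, an endoplasmic reticulum factor of antibody secretion, at 174 and 612 FPKM (a difference of 1.81, but 0.95 without the trend). T cell genes had 6 of 12 higher and 1 lower (median 0.78, percentile 99.7, and 0.63 without the trend), with the CD3 gene Cd3g at 34.2 and 137 FPKM. Of 11 B cell genes 3 were higher and 1 lower, and the median of 0.38 (0.32 without the trend) was within the random range. NK cell genes had 2 of 10 higher and a median of 0.61 (0.07 without the trend) at percentile 98.7, but at percentile 82.3 among random lists also matched on length. Erythroid genes were lower (4 of 14, median -0.37, or -1.18 without the trend), among them the anion exchanger gene Slc4a1 at 77.9 and 14.2 FPKM.

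Ribosomal protein genes were higher in 25 of 28 cases, with a median of 1.19 that stayed outside random lists matched on length (percentile 99.3) but was 0.31 with the length trend removed. All ribosomal protein genes took 5.30% of control counts and 12.4% of mM-CSF counts. Nuclear-encoded oxidative phosphorylation genes had 10 of 24 higher and a median of 0.92 (0.20 without the trend), which lay within random lists matched on length (percentile 91.0). Cell cycle genes had 2 of 30 lower and a median of -0.06 (0.03 without the trend), within the random range.

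Beyond the lists, the 12 highest genes included Stfa1, Cbr2, S100a8, Prtn3, H2ac24, Elane, Pbld1, Prg2, Gpx3, Dapl1 and Camp. Stfa1, a protease inhibitor gene listed at 0 in the control, was at 11.1 FPKM in the mM-CSF library. With the floor on counts it was 13.1-fold higher (lower limit of the counting interval 10.1). The carbonyl reductase gene Cbr2 was at 3.19 and 44.0 FPKM. The 12 lowest were Hspa1b, Hspa1a, Evi2, Cd300ld5, Ace, Cd300ld3, Zfp366, Cbl, Lyst, Cd300ld, Krt80 and Zbed6. Zfp366, a dendritic cell transcription factor gene, was at 24.6 FPKM in the control and 0.17 in the mM-CSF library, and the ubiquitin ligase gene Cbl was at 36.1 and 1.15. Evi2 and Cd300ld5, whose values are uncertain, were at 0 in the mM-CSF library. With the floor on counts they were 372-fold and 57.8-fold lower (lower limits of the counting interval 302 and 46.6).

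The mM-CSF library differed from the control along gene length. Across 9159 genes at 5 FPKM or more on average, Spearman's rho of the difference with length was -0.69, and the median difference went from 0.79 in the shortest 20% of genes (322 to 1478 bases) to -0.84 in the longest (from 4370 bases). Higher genes had a median length of 948 bases and lower genes of 4681, and removal of the trend left 289 higher and 772 lower, of which 157 and 610 were also called with the trend in place. Rescaling each library to TPM moved the median of all genes by -0.45 and the calls to 281 higher and 3406 lower, so that 7.62% of calls were higher instead of 37.2%.

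**Figure D2:**
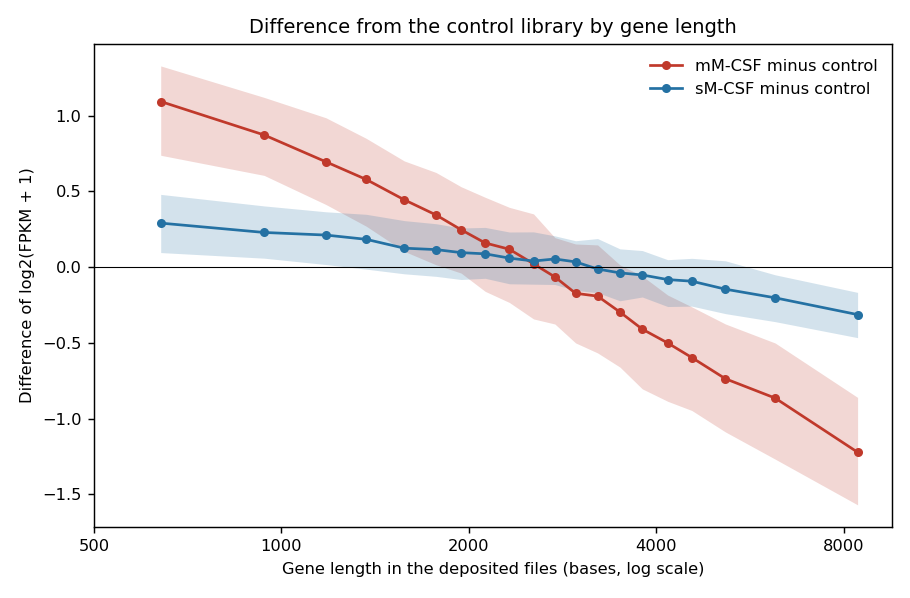
Difference of log2(FPKM + 1) from the control library against gene length in bases on a log axis, over genes at 5 FPKM or more on average. Points are medians of 20 bins of genes and bands span the quartiles. The mM-CSF medians fall along the axis from the shortest to the longest genes (Spearman's rho -0.69), and the sM-CSF medians do so less steeply (rho -0.45).

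The second comparison asks the same of macrophages from leukemia with high sM-CSF. Non-classical monocyte and macrophage genes were lower, and B cell, T cell and MHC class II genes higher. Of 44 lists, some of which share genes, 6 lay above and 19 below the random range, against 7 and 12 in the mM-CSF comparison, although fewer genes passed the size rule. These counts do not compare sizes of change, because the random range was narrower here and smaller medians fell outside it. For macrophage identity genes, the SD of the random lists was 0.085, against 0.217 in the mM-CSF comparison. Ace was at 132 FPKM in the control and 26.5 in the sM-CSF library, a 5.49-fold lower share of counts (95% interval 5.14 to 5.86). Cd79a was at 468 and 958 FPKM, 2.05-fold higher (1.98 to 2.11). By the size rule 76 genes were higher and 158 lower among 9683, and 41 of the higher and 21 of the lower genes were under 300 bases long.

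Of the 12 non-classical monocyte genes 6 were lower, with a median of -0.95 below all random lists. Cx3cr1 was at 46.8 and 14.4 FPKM, Cd300e at 121 and 37.3, and the fatty acid carrier gene Fabp4 at 28.9 and 5.76. Macrophage identity genes had 3 of 18 lower and a median of -0.38, also below all random lists. Lyz2 was at 784 and 282 FPKM, Cebpb at 75.8 and 18.1, and Itgam differed by -1.01, while Csf1r differed by -0.84 and Adgre1 by -0.61, short of the size rule. Red pulp macrophage genes had a median of -0.16 (percentile 0.22), with 1 of 17 higher, namely Trf at 114 and 257 FPKM. Phagocytosis receptor genes had 2 of 18 lower and a median of -0.31, with the Fc receptor gene Fcgr4 at 114 and 38.8 FPKM and the scavenger receptor gene Lrp1 at 47.0 and 21.5. Lipid efflux and storage genes had 2 of 15 lower and a median of -0.37, with the apolipoprotein gene Apoc2 at 30.4 and 10.0 FPKM.

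B cell genes were higher in 3 of 11 cases, with a median of 0.89 (0.77 with the length trend removed). T cell genes were higher in 4 of 12, with a median of 0.79 (0.73 without the trend). Both medians lay above all random lists, and no gene of either list was lower. Without the trend, the higher B cell genes Cd79a, Pax5 and Vpreb3 fell short of 2-fold (0.85, 0.86 and 0.77). Pax5, the B cell commitment factor gene, was at 61.1 and 130 FPKM, and Cd3e at 28.8 and 59.5. None of 12 MHC class II genes passed the size rule, but their median was 0.48 (percentile 99.96, and 0.31 with the length trend removed), with the invariant chain gene Cd74 at 6470 and 9903 FPKM. Ribosomal protein genes had a median of 0.44 (0.22 without the trend) above all random lists, with 0 of 28 past the size rule. Plasma cell, myeloid granule and neutrophil genes lay within the random range, at medians of 0.10, -0.03 and 0.14 (-0.04, -0.07 and -0.04 without the trend), as did conventional dendritic cell genes at -0.13 (-0.08).

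Cell cycle genes were lower as a list, with a median of -0.46 below all random lists, although only the proliferation marker gene Mki67 of 30 passed the size rule, at 69.2 and 33.4 FPKM. Erythroid genes had 2 of 13 lower and a median of -0.60, with Slc4a1 at 77.9 and 29.2 FPKM. The immediate early and heat shock list had a median of -0.38, with Hspa1a and Hspa1b the 2 genes of 19 that were lower. Toll-like receptor genes (-0.32), chemokines (-0.31), colony-stimulating factor genes (-0.39), classical activation genes (-0.21), type I interferon genes (-0.17), lysosome genes (-0.14) and NF-kB feedback genes (-0.13) had medians below the 2.5 percentile, with at most 1 gene of each past the size rule. Complement genes had a median of -0.31 that turned to 0.35 with members at 5 FPKM or more, and marginal zone macrophage genes one of 0.35 (0.20 with the length trend removed) that turned to -0.37. Oxidative phosphorylation genes had a median of 0.22 at percentile 97.6, but at percentile 77.4 among random lists also matched on length, and -0.01 with the length trend removed.

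The highest gene was Pcsk1n (gene 30052), which encodes an inhibitor of a prohormone convertase. It was listed at 0 in the control, at 85.8 FPKM in the sM-CSF library and at 0.11 FPKM in the mM-CSF library. With the floor on counts it was 575-fold higher in the sM-CSF library than in the control (lower limit of the counting interval 467). Its estimated count of 1697 was not whole, and its value is uncertain. Dapl1, Cbr2, Ly6c1, Sap25, Nyx, Ly6k, Lat, Pmel, Lef1, Trf and Cd8b1 followed, of which Lat and Lef1 act in T cells, at 28.4 and 66.6 FPKM and at 11.5 and 27.4 FPKM. The lowest were Cd300ld5, Cd300ld3, Clec4e, Smpdl3b, Tsix, Ace, Nupr1, Ms4a4a, Fabp4, Cebpb, Cd300ld and Zfyve9. Clec4e, a receptor gene for mycobacterial glycolipid, was at 13.5 FPKM in the control and 1.64 in the sM-CSF library.

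A trend with length was also present, at a rho of -0.45, and its removal left 50 higher and 175 lower genes, of which 49 and 134 were called both ways. TPM rescaling moved the median of all genes by -0.14 and the share of higher calls from 32.5% to 21.2%.

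**Figure D3:**
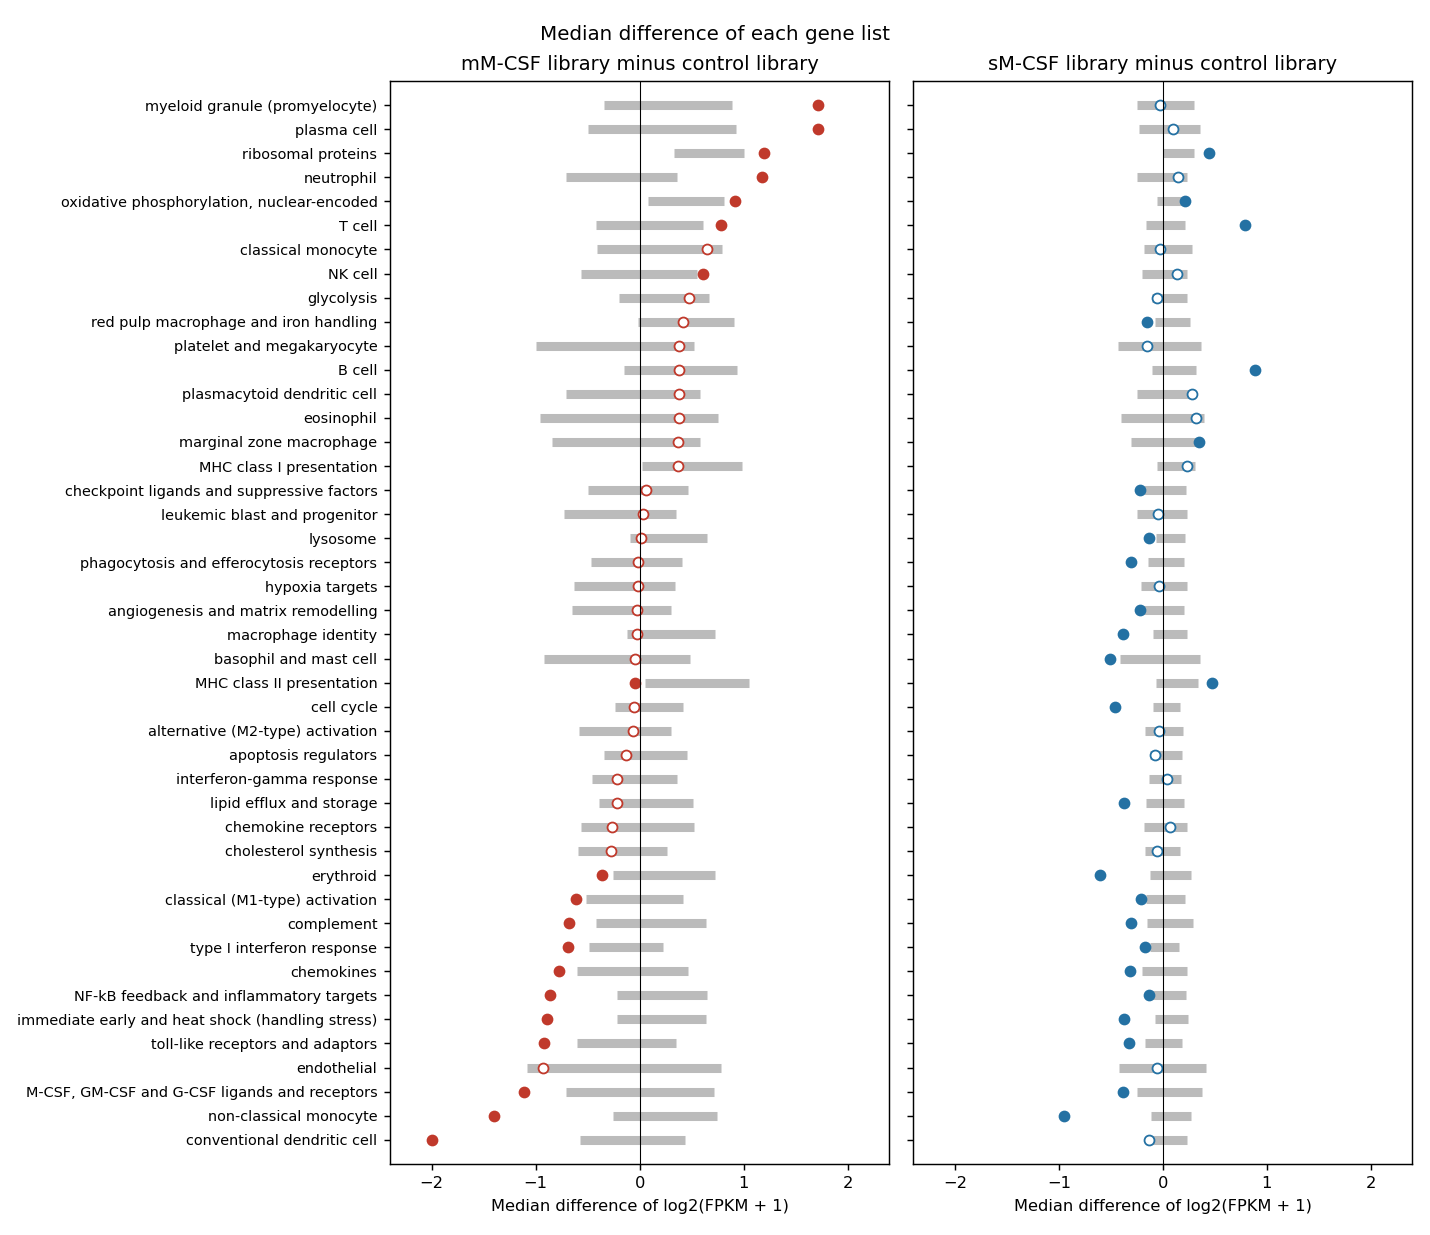
Median difference of log2(FPKM + 1) from the control library for each fixed list (points), with the central 95% of 10000 random lists matched on expression (grey bars). Filled points lie outside the bar. Conventional dendritic cell genes lie at -2.00 in the mM-CSF and -0.13 in the sM-CSF library, non-classical monocyte genes at -1.40 and -0.95, and MHC class II genes at -0.05 (0.02 with median-of-ratios scaling) and 0.48.

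The third comparison sets the mM-CSF and sM-CSF libraries against each other. Granule and plasma cell genes were higher in the mM-CSF library, and conventional dendritic cell, MHC class II, toll-like receptor and NF-kB genes lower. Elane was at 51.7 FPKM in the sM-CSF and 397 in the mM-CSF library, a 7.71-fold higher share of counts (95% interval 6.96 to 8.56). Zbtb46 was at 13.1 and 1.46 FPKM, 8.34-fold lower (5.70 to 12.6). By the size rule 363 genes were higher and 836 lower in the mM-CSF library among 9574.

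Myeloid granule genes had 6 of 8 higher (median 1.79, or 1.53 with the length trend removed), plasma cell genes 6 of 7 (1.60, or 1.20) and neutrophil genes 5 of 13 with 1 lower (0.90, or 0.73). Ctsg was at 17.2 FPKM in the sM-CSF and 92.3 in the mM-CSF library, Mzb1 at 191 and 612, and S100a8 at 15.8 and 122. Cell cycle genes were higher as a list, with 3 of 30 past the size rule and a median of 0.42 (0.56 without the trend), among them the mitotic regulator gene Cdc20 at 20.9 and 48.1 FPKM. Glycolysis genes had a median of 0.52 (0.49 without the trend) with 1 of 18 higher, Tpi1 at 68.8 and 145 FPKM, and 1 lower, Pfkfb3 at 31.7 and 8.22. Red pulp macrophage genes had 5 of 17 higher and a median of 0.64 (0.58 without the trend), at percentile 95.8 of lists matched on expression and 100 of those matched on length too. Spic, the transcription factor gene of red pulp macrophages, was at 88.2 and 201 FPKM, and Csf1r at 149 and 222.

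Conventional dendritic cell genes had 9 of 13 lower and a median of -1.69 (-1.49 without the trend), with Flt3 at 42.0 FPKM in the sM-CSF and 6.25 in the mM-CSF library and the lectin gene Cd209a at 32.0 and 4.25. MHC class II genes had 2 of 12 lower, Ciita and H2-Eb2, and a median of -0.57 (-1.01 without the trend). Medians of the NF-kB feedback, toll-like receptor, type I interferon, classical activation and immediate early lists were -0.73, -0.78, -0.66, -0.62 and -0.51, and -0.80, -0.40, -0.51, -0.71 and -0.24 without the trend. Il1b was at 37.4 and 6.52 FPKM and Tlr9 at 31.7 and 5.41. Non-classical monocyte genes had 4 of 12 lower and 1 higher (median -0.46, percentile 0.67, and -0.45 without the trend), with Ace at 26.5 and 4.09 FPKM. B cell genes had a median of -0.44 (-0.40 without the trend) with 1 of 11 lower, the complement receptor gene Cr2, and T cell genes one of -0.01 within the random range. Ribosomal protein genes were within it too (median 0.73, 0 of 28 past the size rule, percentile 96.7, or 42.7 among lists also matched on length, and 0.06 without the trend). Oxidative phosphorylation and NK cell genes lay above it, at 0.69 and 0.48, but within lists also matched on length. The 6 highest genes were Stfa1, Elane, S100a8, Gstt1, Gpx3 and Prtn3, and the 6 lowest Pcsk1n, Evi2, Hspa1a, Hspa1b, Stra6l and Adam11. The rank correlation with length was -0.67, removal of the trend left 190 higher and 449 lower genes (111 and 333 called both ways), and TPM rescaling moved the median of all genes by -0.31 and the share of higher calls from 30.3% to 7.72%, against 46.5% with median-of-ratios scaling.

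Differences from the control were set side by side for both kinds of M-CSF. Of the genes counted in both comparisons, 42 were higher in both libraries, out of 781 in the mM-CSF and 60 in the sM-CSF library, and 133 were lower in both, out of 1480 and 158 (9557 genes). Independent lists would share 4.90 and 24.5 genes, and libraries simulated with no effect but a shared control 31.0 and 95.3. The simulation gave each gene the same spread in all 3 libraries and held no length trend. The observed differences had an SD of 0.91 for mM-CSF and 0.43 for sM-CSF against control, over genes with the minimum expression. Simulated values of overlap and correlation are thus no exact reference for these libraries. Among the shared lower genes named above were Ace, Cx3cr1, Itgam, Lyz2, Cebpb and Slc4a1. Across 12961 genes the differences correlated with a Pearson's r of 0.62 and a Spearman's rho of 0.65, against a simulated r of 0.50 with no effect. The covariance was 0.24, equal within rounding to the 0.24 simulated with all spread between libraries taken as chance, and 0.21 above the 0.03 simulated with counting noise alone. With the length trend removed it was 0.19. The covariance thus showed no excess over the simulation that takes all spread as chance. Because that simulation took its spread from these same libraries, the match cannot tell a shared response from the lack of one. With 1 control library the controls cannot be split, and part or all of the excess in overlap and in r may come from the shared control.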

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

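The settings on gene length, on genes under 300 bases and the 5 FPKM minimum for lists and the correlation were chosen after the data were seen; the others were planned. No paired analysis was possible because each group has 1 library, which also rules out leaving out a library. The 6 counts of genes (878 higher and 1480 lower for mM-CSF against control, 76 and 158 for sM-CSF against control, 363 and 836 for mM-CSF against sM-CSF) moved with the size rule by construction: 1.5-fold gave 2111 and 2682, 407 and 562, and 1440 and 2119, and 4-fold gave 56 and 278, 17 and 29, and 32 and 110. A pseudocount of 5 FPKM, which shrinks low genes, gave 554 and 780, 38 and 71, and 205 and 332. No minimum or one of 1 FPKM gave 152 and 248 for sM-CSF against control, and a minimum of 20 FPKM gave 33 and 69 there, 654 lower for mM-CSF against control and 349 lower for mM-CSF against sM-CSF. TPM rescaling gave 281 and 3406 for mM-CSF against control, 364 lower for sM-CSF against control, and 182 and 2174 for mM-CSF against sM-CSF, where median-of-ratios scaling gave 551 higher. With the length trend removed the counts were 289 and 772, 50 higher, and 190 and 449 in the same order, and without genes under 300 bases 35 were higher in the sM-CSF library. Other settings kept each count within 1.5 times. Of 131 list medians, 121 moved by less than 1 SD of their random lists with a pseudocount of 0.1, 116 with 5, 22 with TPM and 79 with the length trend removed, where 51 moved by more. Among lists that stood apart from random lists, signs turned for MHC class II in mM-CSF against control (0.0167 with median-of-ratios and 0.0529 with upper-quartile scaling), complement in mM-CSF against control (0.88 and 1.57 with minima of 5 and 20 FPKM) and in sM-CSF against control (0.35 and 0.42), marginal zone macrophages in sM-CSF against control (-0.37 with 5 FPKM) and oxidative phosphorylation in sM-CSF against control (-0.00961 with the length trend removed). For the minima, fewer and more abundant members enter; for the other turns and moves the cause was not tested. The correlation of differences was 0.62, and 0.68 with a minimum of 20 FPKM, where the cause was not tested. It was -0.13 with the sM-CSF library as the shared reference and 0.86 with the mM-CSF library. These values reuse the same pairwise differences and follow from their unequal spreads. Over genes with the minimum expression, the SD was 0.91 for mM-CSF against control, 0.43 for sM-CSF against control and 0.71 for mM-CSF against sM-CSF. At this depth Csf1 rested on 90, 48 and 88 reads, and its ratio of mM-CSF to control had a 95% counting interval of 0.39 to 0.81. That interval does not cover the length trend: the log2 difference of Csf1 was -0.49, but -0.04 with the trend removed.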

Other observations

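Tests on GC content, on the neighbourhood of Pcsk1n and on its shared reads were set out before their results were seen; the tests on length-matched lists, on B and T cell genes, on monocyte against red pulp genes and on other genes restricted to 1 library were chosen afterwards. In several further lists single genes differed most in the mM-CSF library, while the list medians stayed small. The checkpoint ligand gene Cd274, which encodes PD-L1, was at 45.3 FPKM in the control, 7.33 in the mM-CSF and 30.8 in the sM-CSF library, and Havcr2, which encodes TIM-3, at 41.0, 4.80 and 31.9, although the checkpoint list had a median of 0.06 in mM-CSF against control (3 of 14 lower), within the random range, and -0.22 in sM-CSF against control, below it. Among apoptosis regulators (1 of 20 higher and 4 lower in mM-CSF against control, median -0.13, and 0 past the size rule in sM-CSF against control, median -0.07), the BH3-only gene Pmaip1 was at 91.5, 10.5 and 69.6 FPKM. Klf4, of the alternative activation list, was at 39.5, 3.89 and 13.3 FPKM, with list medians of -0.06 and -0.03. The chemokine receptor gene Ccr6 was at 25.1, 5.89 and 26.0 FPKM (list medians -0.27 and 0.07). Kit, a receptor gene of blasts and progenitors, was at 35.0, 6.02 and 34.7 FPKM, while the list of blast and progenitor genes had medians of 0.03 and -0.05. The lipoprotein lipase gene Lpl went the other way, at 15.5 FPKM in the control and 44.7 in the mM-CSF library, in a lipid list with a median of -0.22 in mM-CSF against control, and the eosinophil granule gene Prg2 was at 11.9, 88.5 and 25.6 FPKM (list medians 0.37 and 0.32).

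The alternative activation, chemokine receptor, blast and progenitor, and eosinophil lists lay within the random range in both comparisons with the control. Apoptosis regulators did so too, but lay at percentiles 1.68 (mM-CSF) and 1.80 (sM-CSF) of random lists also matched on length. Further lists within the range in both, mM-CSF first, were interferon-gamma response (-0.21 and 0.04), MHC class I presentation (0.36 and 0.23), cholesterol synthesis (-0.28 and -0.05), hypoxia targets (-0.02 and -0.04), classical monocytes (0.64 and -0.03), platelets (0.38 and -0.15), plasmacytoid dendritic cells (0.38 and 0.28) and endothelium (-0.93 and -0.06). In mM-CSF against control, lysosome (0.01), phagocytosis (-0.02), angiogenesis and matrix (-0.02), marginal zone macrophage (0.37), lipid (-0.22) and basophil and mast cell genes (-0.05) were within it too. Glycolysis genes (0.48, or 0.34 with the length trend removed) were within it, but at percentile 99.9 of random lists also matched on length. With the length trend removed, the mM-CSF medians were -0.11 for classical monocytes, 0.01 for MHC class I, -0.38 for endothelium, -0.39 for alternative activation and -0.57 for basophil and mast cell genes. In sM-CSF against control, angiogenesis (-0.22, or -0.10 with the trend removed), checkpoint (-0.22) and basophil and mast cell genes (-0.50) lay below it, and glycolysis (-0.06) and NK cell genes (0.14) within it. Of 10 stromal fibroblast genes 1 was measured. Xist, the RNA of the inactive X chromosome, was at 120.0 FPKM in the control, 25.4 in the mM-CSF and 61.4 in the sM-CSF library, and Tsix, antisense to it, at 24.5, 1.60 and 3.93. In mM-CSF against control, the difference of the long Xist was -2.20, but -0.98 with the length trend removed. That of Tsix was -3.29, and -2.76 with the trend removed. The Y-linked gene Ddx3y did not pass 0.10 FPKM in any library.

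In the mM-CSF library, short genes were higher and long genes lower than in the control. The test argued against GC content as the source, since rho with length was still -0.66 after the GC trend was removed, 95.4% of its size over 9081 genes with a known GC content. Length by itself did not account for the difference of every group from the control: against lists matched on expression and length, ribosomal protein genes lay at percentile 99.3 (99.26) and non-classical monocyte genes at percentile 0, although against the sM-CSF library ribosomal protein genes lay at percentile 42.7, within the range. What gives the trend stays open, because the library, its preparation and the mM-CSF group are one and the same here. With the trend removed the ribosomal protein median shrank from 1.19 to 0.31, and the non-classical monocyte median went from -1.40 to -1.82.

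In the sM-CSF library, lymphocyte genes were higher and non-classical monocyte genes lower than in the control. That 100% of the 23 measured B and T cell genes lay above the median of all genes restates the first part, so a larger share of lymphocytes among the sequenced cells and other causes of it stay open. For the second part, the difference of medians between non-classical monocyte and red pulp macrophage genes was -0.87. Its 95% bootstrap interval over genes was -1.74 to -0.43. The test cannot decide on dilution of all macrophages by other cells, because it assumes that those cells express neither list. It was also chosen after the low monocyte values were seen. Macrophage identity genes were lower too (median -0.38, 16 of 18 below 0), whereas Trf of the red pulp list was higher. A lower share of the monocytes themselves, or lower expression in them under sM-CSF, stays open as a hypothesis that 1 library per group cannot test.

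Pcsk1n was at 85.8 FPKM in the sM-CSF library, from an estimated count of 1697.43, against 0 counts in the control and 2 in the mM-CSF library. Reads shared with another gene may contribute, as the count was not whole, but this holds for many genes and is weak evidence, and whether the reads come from macrophages, from cells carried along in the sort, from a construct in the leukemia cells or from wrong mapping stays open. Apart from Pcsk1n, 0 genes had at least 100 counts there and at most 5 in each of the others. This cannot decide on reads of another annotated gene restricted to this library. A gene whose reads were assigned to Pcsk1n need not show counts of its own. The 10 nearest measured genes differed by -0.80 to 1.20, so none of them shared a difference of the size of Pcsk1n (6.44). Whether the neighbourhood was slightly more active cannot be told apart from chance: the median of these genes was 0.32 (bootstrap interval 0.19 to 0.51), at the edge of the central 95% of 12754 runs of adjacent genes (-0.28 to 0.33).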
